A study of Mus musculus with 8 samples.

How the data were processed

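Single-cell RNA sequencing (10x Genomics 3' kit) was carried out on subcutaneous tumours of MC38, a mouse colon carcinoma cell line, collected on day 14 from mice with 2 genotypes. WT mice carried no modified CD64 allele, and CD64-hDTR mice carried 1 modified and 1 unmodified allele. CD64 is a high-affinity receptor for IgG found mainly on macrophages and monocytes, and CD45 is a surface protein of leukocytes. Every sample carries the treatment label DT. In batch 1, live cells were sorted without surface markers and 15000 cells were loaded per genotype. In batch 2, live cells were sorted through 3 gates (CD45-, CD45+CD64+ and CD45+CD64-) and 10000 cells were loaded per library. The labels give 8 libraries in 8 groups, 1 library per combination of genotype, gate and batch. Groups follow the titles and the genotype field. A free-text description names the WT genotype for every sample and was not used for grouping.

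The deposited matrices hold counts of unique molecular identifiers per gene and barcode, made with Cell Ranger 6.0.0 in batch 1 and Cell Ranger 7.1.0 in batch 2, per the file headers. The genome build was mm10, per the submitters' processing notes. Batch and software version cannot be told apart. The authors' counts were used as deposited, with no normalisation. Each matrix has 32285 rows, and the gene and barcode lists that go with the rows and columns were not used here, so no row could be tied to a gene. Gene lists, cell type markers and named genes fixed before the data were examined (among them the genes in the study's title) could not be applied, the targeted allele could not be checked in the counts, and cell types stay unnamed. The mitochondrial filter of 10% described by the submitters was not applied for the same reason. Rows were matched across libraries by position. The Pearson correlation of log CPM (counts scaled to the same total per library) between libraries ranged from 0.897 to 0.997 across rows.

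The 8 libraries hold 61262 barcodes. Following the submitters' description, cells with under 1000 detected features (matrix rows with a count) were left out, which kept 48242. Doublets were scored by Scrublet's method, written anew in Python. Its automatic threshold marked at most 0.0750% of barcodes in all but 1 library, so, as a rule chosen after seeing this, the highest-scoring barcodes were removed instead, at an expected share of 0.8% per 1000 barcodes, which left 44335 cells. In a simulated mixture of 3000 cells with 90 doublets across gates, 61.1% of the doublets lay in the top 5% of scores. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable rows and 30 principal components entered a graph of 15 neighbours, which was clustered with the Leiden algorithm at a resolution of 0.5 over all libraries together, without batch correction. Joint clusters under 100 cells (3 clusters, 161 cells) were left out. Where each batch was clustered separately, the 8 clusters under 100 cells (441 cells) were kept. Clusters are given by number and described by the gates of the batch 2 cells in them.

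Each batch 1 cell was assigned to the gate it most resembled with a logistic classifier on 300 rows per gate, trained on the sorted libraries of batch 2. The classifier was tested by training on 1 genotype and scoring the other. Counts were then summed per genotype and batch over the cells of each gate class, which gave 4 sums per class (2 per genotype). Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, batch and genotype as terms, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. This leaves 1 residual degree of freedom, so the estimate of the spread rests largely on sharing between rows. The labels do not say how many animals a library holds, so p-values do not measure the spread between animals. Prior degrees of freedom, the weight of the sharing, were 76.6, 176 and 10.6 in the CD45-, CD45+CD64+ and CD45+CD64- classes. A small p-value or standard error therefore does not show that a row changed by a like amount in both batches. Log2 fold changes are CD64-hDTR over WT with standard errors derived from the test statistic. On counts simulated from the sums with 200 rows changed, the test recovered 82.7% of 2-fold and 100% of 4-fold changes among 19145 rows of the CD45- class, 47.9% and 95.8% among 17018 rows of the CD45+CD64+ class, and 0% and 12.8% among 16466 rows of the CD45+CD64- class. It made 6, 6 and 0 false calls in these classes. The simulation gave all rows of a class the same dispersion and a changed row the same fold in both batches. Only rows above a minimum count were changed. This is a best case for a test that shares the spread between rows, so these rates need not hold for the data.

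Comparisons of a pair of libraries have no replicate and no test. Shares are given with exact (Clopper-Pearson) 95% binomial intervals and sums of counts with exact 95% Poisson intervals, which cover counting error only. Across-row correlations of log2 ratios used CPM plus a pseudocount of 1, computed from the deposited counts, and rows with at least 100 counts over the 4 sums. Matrix rows are given by number for at most 2 higher and 2 lower rows per class: those of largest fold past the threshold, in the same direction in both batches, with at least 1000 counts over the 4 sums. Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no count filter, no batch term, doublets kept, minimums of 500 and 2000 features, a batch 1 class probability of at least 0.9, thinning of sums or cells (to 1500 counts per cell), other reference sets and classifiers, a Leiden resolution of 1.0, clustering of each batch separately and a minimum of 1000 counts for the correlations. Classes defined by clusters of each batch, with and without clusters whose share differed over 4-fold between genotypes, were added after seeing the data, as were values of named rows by cluster within the gate's own libraries, with and without the cluster holding most counts. Computations used Python 3.11.15 with scikit-learn 1.9.0, scipy 1.17.1 and leidenalg 0.10.2.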

Results

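To examine tumours after targeting of CD64-expressing cells, single-cell transcriptomes of MC38 tumours from WT and CD64-hDTR mice were compared in an unsorted batch of live cells (batch 1) and in a batch sorted into CD45-, CD45+CD64+ and CD45+CD64- cells (batch 2). Each genotype had 1 library per gate and batch, so values of single libraries have no replicate. In batch 1, the WT library held 15228 barcodes and 233394591 counts, and the CD64-hDTR library held 8201 barcodes and 117232254 counts. The CD45- libraries held 6013 barcodes and 171040522 counts in WT and 8259 barcodes and 212353613 counts in CD64-hDTR. The CD45+CD64+ libraries held 5435 barcodes and 124505172 counts in WT and 4185 barcodes and 122432948 counts in CD64-hDTR. The CD45+CD64- libraries held 9632 barcodes and 69292800 counts in WT and 4309 barcodes and 58286307 counts in CD64-hDTR. The same number of cells was loaded for each sorted library, so the number of barcodes does not measure how common a population was in the tumour.

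The first question was how the cells within each gate differed between genotypes. In the CD45+CD64+ gate, joint cluster 3 held 56.8% of WT cells (95% interval 55.3 to 58.3) and 40.6% of CD64-hDTR cells (39.0 to 42.2). Joint cluster 10 went the other way, with 2.85% of WT cells (2.37 to 3.40) and 23.3% of CD64-hDTR cells (22.0 to 24.7). Joint cluster 18, whose cells had a median of 48998.5 counts, held 6.89% of WT and 2.83% of CD64-hDTR cells. Cells of cluster 10 were also sorted as CD45+CD64-, at 10.7% of that gate in WT and 7.57% in CD64-hDTR. Batch 2 cells made up 98.2% of cluster 3 and 97.6% of cluster 10. Of the unsorted libraries, cluster 3 held 0.0274% of WT (0.00565 to 0.0800) and 1.57% of CD64-hDTR cells (1.24 to 1.96), and cluster 10 held 0.310% and 0.209%, with overlapping intervals. Joint clustering used no batch correction, so the shares of the batches are not read against each other. The differences within the CD45+CD64+ gate exceeded counting error, and with 1 library per genotype no replicate spread was available. The share of cluster 3 dropped by 16.3 percentage points, and that of its closest match dropped by 25.4 points at a Leiden resolution of 1.0.

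**Figure D1:**
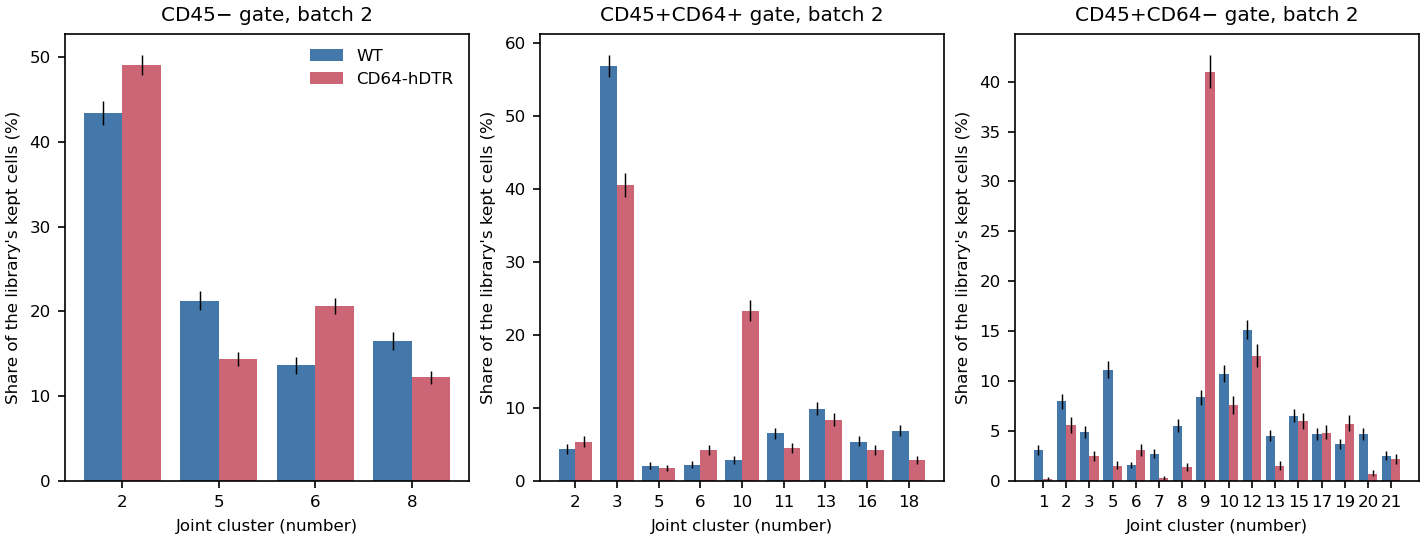
Share of each sorted library's kept cells (y axis, percent) in joint clusters (x axis, cluster number) that held at least 2% of a library, for WT (blue) and CD64-hDTR (red); error bars are exact 95% binomial intervals for 1 library each. Cluster 10 rose from 2.85% to 23.3% in the CD45+CD64+ gate and cluster 9 from 8.37% to 41.0% in the CD45+CD64- gate.

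In the CD45+CD64- gate, the largest difference was in joint cluster 9, which held 8.37% of WT cells (7.64 to 9.15) and 41.0% of CD64-hDTR cells (39.4 to 42.7). Cells of this cluster had a median of 6968.5 counts. Batch 2 cells made up 96.9% of the cluster, and 0.0912% of WT and 1.07% of CD64-hDTR cells of the unsorted libraries lay in it, which is likewise not read against the gate. Joint cluster 20 held 4.69% of WT cells and 0.719% of CD64-hDTR cells of the gate, whereas cluster 12 held 15.1% and 12.5%. The gate also held cells of clusters assigned to other gates. By clusters of batch 2 alone, 45.9% (44.5 to 47.2) of the WT CD45+CD64- library and 74.3% (72.8 to 75.7) of the CD64-hDTR library were of the CD45+CD64- type, and 32.4% and 12.7% were of the CD45- type. Some assignments were weak. Cluster 9, assigned to CD45- at 47.3% with libraries weighted equally, held 8.84% of the WT CD45+CD64- and 6.42% of the WT CD45- library. Cluster 8, assigned to CD45+CD64+ at 57.6%, held 10.7% of the WT CD45+CD64- and 2.90% of the WT CD45+CD64+ library. These type shares are therefore uncertain.

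In the CD45- gate, 99.2% of WT and 99.5% of CD64-hDTR cells belonged to clusters of the CD45- type. Joint cluster 2 held 43.4% of WT cells (42.0 to 44.8) and 49.1% of CD64-hDTR cells (47.9 to 50.2), cluster 6 held 13.6% and 20.7%, cluster 5 held 21.3% and 14.3%, and cluster 8 held 16.5% and 12.2%. The median count per cell was 5198 in cluster 6, against 26093 in cluster 2, 45638 in cluster 5 and 34804.5 in cluster 8. Most batch 1 cells lay in other joint clusters: cluster 1 held 55.2% of the WT and 36.5% of the CD64-hDTR unsorted library, and cluster 4, with a median of 3902 counts per cell, held 14.8% and 37.3%. They held 342 and 38 batch 2 cells, too few to describe them by gate.

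A further question was whether CD45+CD64+ cells were scarcer in CD64-hDTR tumours. This could be asked only in batch 1, which was not gated on CD64. Batch 1 cells assigned to the CD45+CD64+ gate made up 9.44% of WT cells (8.89 to 10.0, 1034 of 10959) and 9.33% of CD64-hDTR cells (8.52 to 10.2, 446 of 4778), a difference not detectable at this depth. The assignment depended on the reference: with the WT libraries alone as reference, the shares were 7.87% in WT (7.37 to 8.39) and 5.80% in CD64-hDTR (5.15 to 6.50), and with the CD64-hDTR libraries alone they were 6.33% and 6.34%. Trained on WT, the classifier placed 49.9% of the CD64-hDTR CD45+CD64+ library in its own gate and 40.2% in the CD45+CD64- gate. Trained on CD64-hDTR, it placed 94.5% of the WT CD45+CD64+ library in its own gate.

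**Figure D2:**
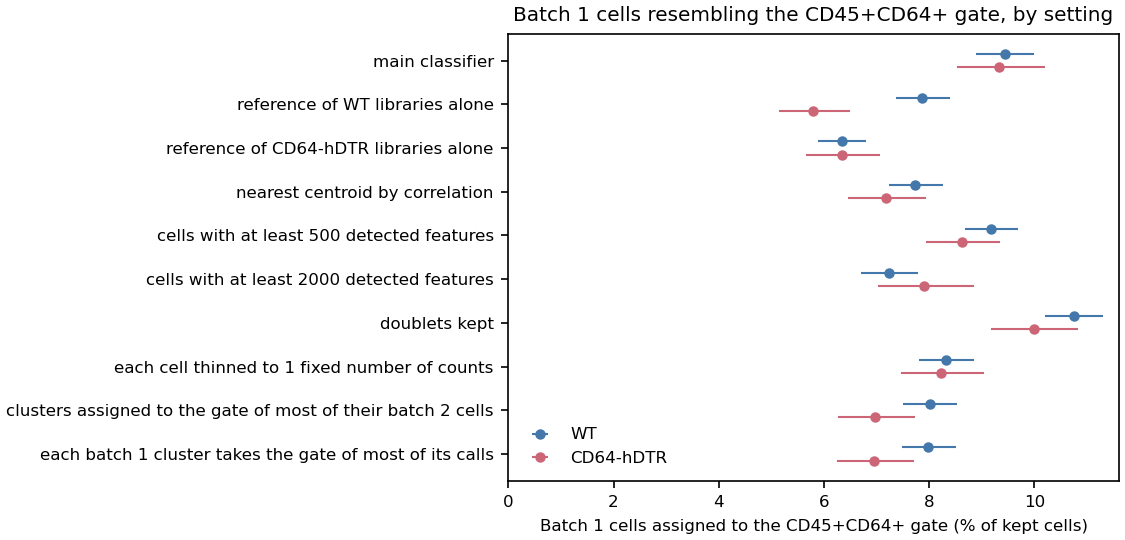
Percent of kept batch 1 cells assigned to the CD45+CD64+ gate (x axis) under each setting (y axis), for the WT (blue) and the CD64-hDTR (red) library; points are shares and bars exact 95% binomial intervals. The main shares were 9.44% and 9.33%, and the interval of CD64-hDTR lies below that of WT with WT libraries alone as reference (5.80% against 7.87%).

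Genotype effects within the CD45+CD64+ class were tested on sums of counts per genotype and batch. Of 17385 matrix rows tested, 1007 rose and 636 fell in CD64-hDTR. Row 19798 fell from 245 to 53.9 CPM in batch 1 and from 400 to 15.5 CPM in batch 2 (log2 fold change -3.47 ± 0.29 SE, n = 2 sums per genotype, edgeR adjusted p = 4.23e-21). When each batch was clustered separately, it was lower in each of the 7 batch 2 clusters of the CD45+CD64+ type that had at least 30 cells of both genotypes in the gate's own libraries, with no overlap of Poisson intervals. In the largest of them, cluster 2 of batch 2, it stood at 528 CPM in WT and 33.2 CPM in CD64-hDTR. In cluster 7 of batch 1, the only cluster of this type in that batch with enough cells, it stood at 290 and 60.5 CPM. Row 6874 fell as well, with 5.43 and 2.31 CPM in batch 1 and 8.38 and 0.529 CPM in batch 2 (log2 fold change -2.99 ± 0.36 SE, edgeR adjusted p = 8.04e-12). Its call ended when clusters with shares over 4-fold apart between genotypes were left out (-2.54, edgeR adjusted p = 0.0826, range 8.57e-16 to 0.965 over its alternatives).

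**Figure D3:**
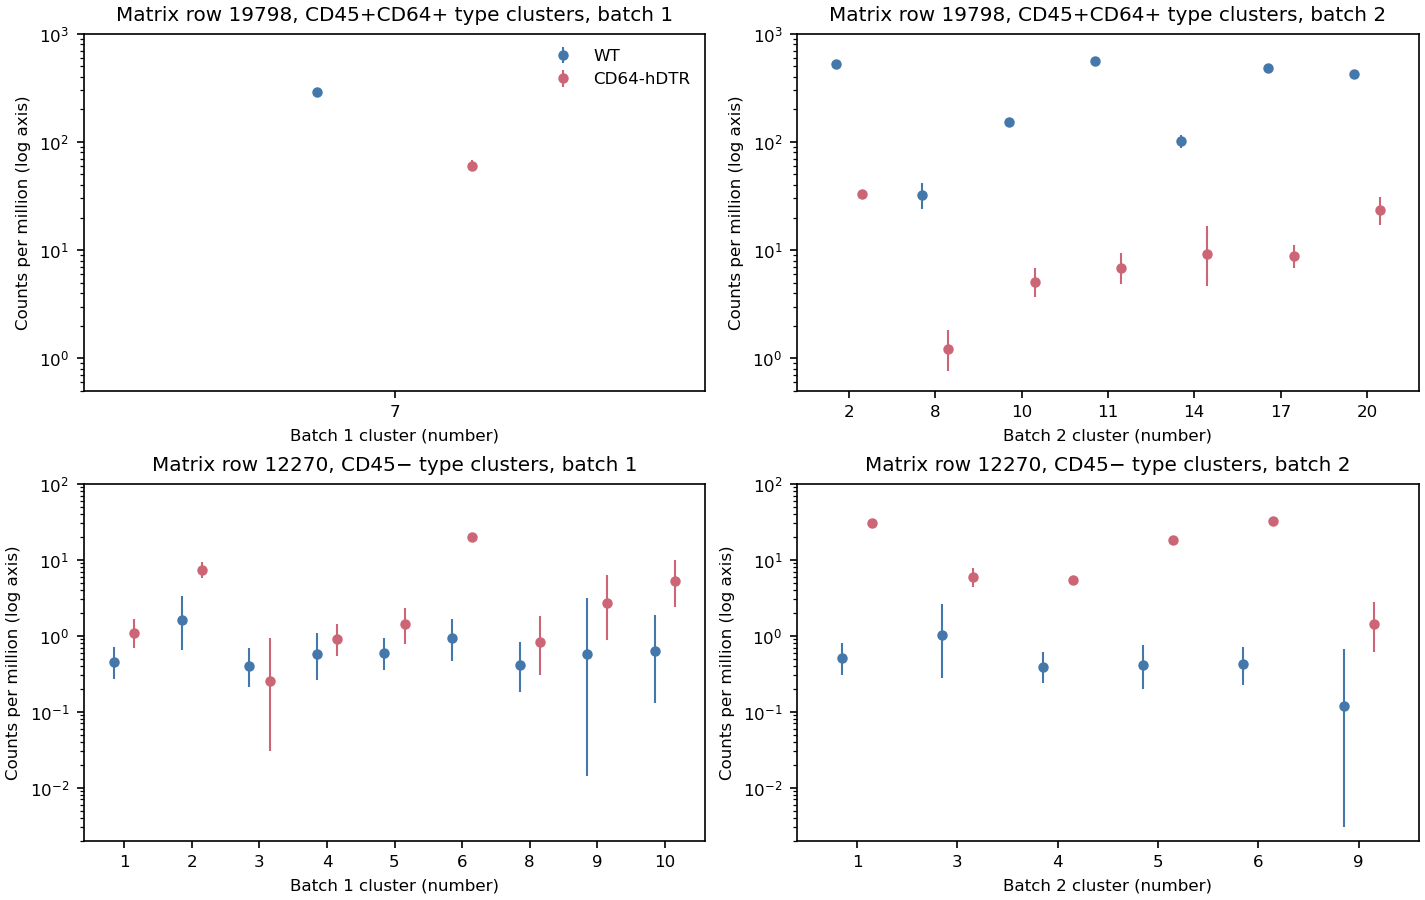
CPM on a log axis (y) of the matrix row of largest fall in the CD45+CD64+ class (19798) in clusters of the CD45+CD64+ type (top) and of that of largest rise in the CD45- class (12270) in clusters of the CD45- type (bottom), by cluster number (x) of batch 1 (left) and batch 2 (right), for clusters with at least 30 cells of both genotypes; points are sums over cells of 1 library, in batch 2 that of the named gate, of WT (blue) or CD64-hDTR (red) and bars exact 95% Poisson intervals. Row 19798 was lower in CD64-hDTR in all 7 batch 2 clusters shown, and row 12270 was higher in all 6 batch 2 clusters shown.

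Among rows that rose in the CD45+CD64+ class, row 2224 went from 0.221 to 17.8 CPM in batch 2 and from 0.452 to 2.95 CPM in batch 1 (log2 fold change 5.78 ± 0.43 SE, edgeR adjusted p = 1.21e-25). Row 26660 went from 0.283 to 17.3 CPM in batch 2 and from 0.362 to 9.10 CPM in batch 1 (log2 fold change 5.73 ± 0.36 SE, edgeR adjusted p = 9.68e-32). Both rows had higher levels in a cluster of the CD45+CD64- type, cluster 7 of batch 2, where row 2224 stood at 427 CPM in WT and 862 CPM in CD64-hDTR, and row 26660 at 1916 and 3444 CPM. With classes defined by clusters the log2 fold change of row 26660 was 4.19 (edgeR adjusted p = 0.00247, range 2.12e-53 to 0.731 over its alternatives). It then rested on batch 2, since batch 1 held 3 WT and 2 CD64-hDTR counts by cluster, with no rise. Of these, 2 and 2 lay in cluster 7 (0.218 and 0.395 CPM). In batch 2, row 26660 had 564 CD64-hDTR counts by cluster. Few cells held most of them: 274 lay in 23 of the 797 cells of cluster 8 and 188 in 15 of the 358 cells of cluster 10. Of the 1716 CD64-hDTR counts that row 2224 had in batch 2 by cluster, 1532 lay in cluster 8, and without this cluster it stood at 0.0872 CPM in WT and 2.40 CPM in CD64-hDTR. With classes defined by clusters, and clusters whose share differed over 4-fold between genotypes left out (chosen after seeing the data), 178 rows were called, and without a batch term edgeR called 0 rows, with 892 at an unadjusted p under 0.05. The DESeq2 Wald test called 655.

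In the CD45- class, 581 of 19623 tested rows rose and 467 fell in CD64-hDTR. The split differed with DESeq2 size factors, where 824 rose and 1115 fell. The prior degrees of freedom also went from 76.6 to infinite there, so the scaling alone is not shown as the cause. The DESeq2 Wald test, which also differs in its test, dispersion and filtering and gave no adjusted p for 12935 rows, called 147 higher and 493 lower. Row 12270 rose from 0.542 to 23.2 CPM in batch 1 and from 4.47 to 46.0 CPM in batch 2 (log2 fold change 4.08 ± 0.19 SE, edgeR adjusted p = 1e-29). Few cells held most of its CD64-hDTR counts. By clusters, 1697 of the 2115 CD64-hDTR counts of batch 1 lay in 2 of the 12 cells of cluster 17, where 14 WT cells had 0 counts, and without this cluster the row stood at 0.550 CPM in WT (0.442 to 0.676) and 4.53 CPM in CD64-hDTR (4.11 to 4.99). Of the other 418 CD64-hDTR counts of batch 1, 276 lay in 15 of the 504 cells of cluster 6. In the CD45- libraries, 24 of the 49 CD64-hDTR cells of cluster 24 held 4798 of 8632 counts, and 2 of the 19 WT cells of that cluster held 634 of 701 counts. Of the other 3834 CD64-hDTR counts, 1861 lay in 145 of the 2285 cells of cluster 1. Without cluster 24 the row stood at 0.430 CPM in WT and 20.6 CPM in CD64-hDTR, with no overlap of intervals. The row was higher in CD64-hDTR in each of the 6 other clusters of these libraries that could be compared, 5 of them with no overlap of intervals, and in 8 of 9 clusters of batch 1, 3 of them with no overlap. Poisson intervals take counts as independent, so they are too narrow where few cells hold most counts. The row was not particular to this gate, at 1.01 CPM in WT and 35.6 CPM in CD64-hDTR in the CD45+CD64+ gate. Row 4879 rose from 0.529 to 1.92 CPM in batch 1 and from 0.0829 to 7.64 CPM in batch 2 (log2 fold change 3.62 ± 0.39 SE, edgeR adjusted p = 3.22e-11). Cluster 7 of batch 2, of the CD45+CD64- type, held 30160 CPM of this row in WT and 72390 CPM in CD64-hDTR. With classes defined by clusters the fold of row 4879 was 1.17 on the log2 scale and no longer passed (edgeR adjusted p = 0.0905, range 1.35e-37 to 1 over its alternatives), and neither did it with a minimum of 2000 features (1.22, edgeR adjusted p = 0.0684).

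Rows 7087 and 29731 fell in the CD45- class. Row 7087 went from 15.4 to 4.33 CPM in batch 1 and from 16.6 to 2.71 CPM in batch 2 (log2 fold change -2.38 ± 0.16 SE, edgeR adjusted p = 2.36e-21). Row 29731 went from 3.64 to 1.06 CPM in batch 1 and from 3.23 to 0.495 CPM in batch 2 (log2 fold change -2.40 ± 0.24 SE, edgeR adjusted p = 1.91e-12). Both were abundant in the CD45+CD64+ gate, at 3331 and 732 CPM in the WT library and 1244 and 259 CPM in the CD64-hDTR library. With classes defined by clusters row 7087 still fell (log2 fold change -1.79, edgeR adjusted p = 2.33e-05, range 2.82e-57 to 1 over its alternatives). It then had 88 WT and 33 CD64-hDTR counts in batch 2, against 2610 and 510 before. Row 29731 then had 32 WT and 10 CD64-hDTR counts in batch 2, against 507 and 93 before (log2 fold change -1.75, edgeR adjusted p = 0.0046, range 8.92e-22 to 1 over its alternatives). Row 7087 was lower in all 9 batch 1 clusters compared, each with no overlap of intervals. In batch 2 it was lower in 5 of 6, 4 with no overlap, and higher in 1 with no overlap. Row 29731 was lower in 9 of 9 in batch 1, 7 with no overlap. In batch 2 it was lower in 5 of 6 and higher in 1, with overlapping intervals in each. The class as a whole gave 304 higher and 174 lower rows by cluster. The median log2 fold in the direction of the call was 0.62 over the 1045 of the 1048 calls that were tested, all of the same sign, against 0.63 before, while the prior degrees of freedom went from 76.6 to 17.4. Without a batch term edgeR called 0 rows, with 126 at an unadjusted p under 0.05.

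In the CD45+CD64- class, 67 of 16950 tested rows rose and 0 fell by edgeR, with 630 rows at an unadjusted p under 0.05. The DESeq2 Wald test called 99 higher and 1 lower. Other edgeR fits called falls as well, with 1085 higher and 531 lower at a minimum of 2000 features, 642 and 39 with classes by cluster, 213 and 12 at a class probability of at least 0.9, 232 and 7 with no count filter and 157 and 3 with doublets kept. With classes defined by clusters, and clusters of shares over 4-fold apart left out (chosen after seeing the data), 12 rows were called higher and 11 lower, and 6 of the 67 calls (8.96%) were made again in the same direction. When as many cells were left out at random, 307 were called higher and 9 lower, and 57 (85.1%) were made again. The median log2 fold in the direction of the call was 3.23 over the 67, 0.98 over the 40 still tested without those clusters and 2.90 over the 62 tested with random cells left out. The class had 2955938 WT counts and 2356697 CD64-hDTR counts in batch 1, against 52037835 and 53358022 in batch 2. Its batch 1 cells depended on the method, at 626 WT and 380 CD64-hDTR cells by the classifier and 102 and 161 by cluster. Their share of batch 1 was 12.3% in WT and 19.7% in CD64-hDTR with WT libraries alone as reference. With CD64-hDTR libraries alone it was 0.0547% and 0.733%. The batch 1 sums of this class may thus hold cells of other types. The rows of largest fold rested on batch 2: row 16829 had 19 WT and 1661 CD64-hDTR counts in batch 2 and 0 and 1 counts in batch 1, and row 4305 had 72 and 4749 counts in batch 2 and 1 and 1 counts in batch 1. With doublets kept, row 4305 had a log2 fold change of 1.51 and no longer passed (edgeR adjusted p = 0.0702, range 3.76e-33 to 1 over its alternatives). In the CD45+CD64- libraries, 1644 CD64-hDTR counts of row 16829 lay in 29 of the 1419 cells of cluster 7, and 6 WT counts in 5 of 446 cells. Cluster 25 of batch 2 has 53 cells, 44 of them from the CD64-hDTR CD45+CD64- library, and these held 4651 of the counts of row 4305. The number of calls ranged from 0, with sums thinned to the smallest, to 1616, with a minimum of 2000 features, which left 4 WT cells of this class in batch 1.

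Genotype effects were then compared between batches, which shared no libraries. Across 17048 rows of the CD45- class the log2 ratios of the batches correlated with a Pearson r of 0.52 and a Spearman rho of 0.52, and 73.3% of rows had the same sign. Across 15394 rows of the CD45+CD64+ class r was 0.54 and rho was 0.48, with 62.6% of the same sign. Across 14823 rows of the CD45+CD64- class r was 0.04 and rho was -0.11, with 46.2% of the same sign, whereas with classes defined by clusters (chosen after seeing the data) r was 0.25 and rho was 0.23 across 12188 rows, with 56.5% of the same sign. The batch 1 cells of the CD45+CD64- class depended on the method of assignment, so its r is not read as a lack of agreement. Rows are not independent replicates, so no p-value is given. A test of the difference in genotype effect between classes, fitted over all 12 sums, called 0 of 20279 rows by edgeR for CD45+CD64+ against CD45- (1261 at an unadjusted p under 0.05), 0 for CD45+CD64+ against CD45+CD64- (1111) and 0 for CD45- against CD45+CD64- (695). The batch 1 sums of all classes of a genotype come from 1 library, and the fit took them as independent. No simulation was run for this test, so its power is not known. The calls of the classes are thus not shown to differ between them, nor shown to be alike.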

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

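The test of doublets and that of fewer cells below were written before their results were seen, while those of a single library, of RNA from other cells, of other cells in the class and of cluster make-up were chosen or reworded after the result was seen.

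Barcodes with under 1000 detected features, which enter no comparison, made up 37.3% (36.3 to 38.4) of the CD64-hDTR unsorted library and 16.9% (16.3 to 17.5) of the WT unsorted library. They held 3.97% and 1.65% of the counts. In the 3 sorted pairs the difference went the other way, at 7.58% in CD64-hDTR and 16.2% in WT for CD45-, 9.84% and 18.2% for CD45+CD64+, and 16.4% and 38.1% for CD45+CD64-.

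When each batch was clustered separately, cluster 15 of batch 2 held 0.165% of the WT and 13.3% (12.2 to 14.5) of the CD64-hDTR CD45+CD64+ gate, 7 and 486 cells, and cluster 13 of batch 1 held 1 WT and 66 CD64-hDTR cells. A quirk of 1 library is argued against by the match of these clusters across batches within CD64-hDTR cells (Pearson r of 0.846 across matrix rows, which are not independent replicates, against 0.187 for the next cluster). Doublets of other clusters are argued against by 80 matrix rows that lay over 2-fold above each of the 23 other clusters compared. However, the 512 CD64-hDTR cells of cluster 15 over all sorted gates had a median of 42811 counts. The median of the CD64-hDTR CD45+CD64+ library was 26256. A genotype effect may remain as a hypothesis. A difference between the animals used stays open, since the labels do not say how many there were or whether the batches shared them.

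Of the 467 matrix rows lower in the CD45- class, 7.71% stood at least 10 times higher in the CD45+CD64+ gate of WT, against 10.7% of those higher. The WT CD45- sum of batch 2 entered both this ratio and the calls. That tends to lower the ratio of rows called lower and to raise that of rows called higher. The comparison therefore cannot decide whether RNA from CD45+CD64+ cells was a cause. For the 36 rows called lower that stood 10 times higher, cells of the CD45+CD64+ type counted in the class remain a possible explanation for batch 2. With classes by cluster 16.7% of these rows were called lower again. RNA from CD45+CD64+ cells outside those cells was not tested for the 36 rows alone and is not excluded. Of all 1048 calls of the class, 45.3% were made again in the same direction there, as prior degrees of freedom fell from 76.6 to 17.4. A lost call alone therefore does not point to such cells. Their median level, as a percent of that in the same genotype's CD45+CD64+ class, went from 0.519% to 0.0277% in WT and from 0.359% to 0.0575% in CD64-hDTR. This percent then stood higher in CD64-hDTR than in WT. In batch 1 it went from 0.393% to 0.333% in WT and from 0.276% to 0.221% in CD64-hDTR. The percent also depends on the CD45+CD64+ level, which was lower in CD64-hDTR for rows 7087 and 29731 of the 36. By cluster, row 7087 stayed lower in the CD45- class in batch 2, at 0.563 CPM in WT and 0.176 CPM in CD64-hDTR. The higher percent is thus not read as a reversal. The share called again lies between the bounds set for the test. In batch 2, row 7087 went from 2610 to 88 counts in WT and from 510 to 33 in CD64-hDTR by cluster. Row 29731 went from 507 to 32 and from 93 to 10. The cells left out there included 34 WT and 30 CD64-hDTR cells of the CD45+CD64+ type. Cells outside clusters of the CD45- type thus held most batch 2 counts of these rows in the class. For the remaining counts and for batch 1, such cells, RNA from CD45+CD64+ cells outside them and a change within CD45- cells cannot be told apart.

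Of the 1643 calls in the CD45+CD64+ class, 10.2% were made again in the same direction when clusters with shares over 4-fold apart were left out (178 calls), against 62.8% when as many cells were left out at random (1141 calls), which argues against the loss of cells as the cause. The clusters were built from the same counts and were left out because their shares differed between genotypes. A change of expression that places cells in a cluster of their own would be left out too, which random removal does not control for. The test therefore cannot tell a shift in cluster make-up from such a change, and either may account for part of these calls. The median log2 fold in the direction of the call was 1.07 (quartiles 0.83 to 1.52) with classes by cluster, 1.07 with random cells left out and 0.66 (0.39 to 1.09) without those clusters, where 97.2% kept their sign. Calls ended as folds became smaller, but the prior degrees of freedom also fell. They were 13.3 with classes by cluster, 8.68 with random cells left out and 5.4 without those clusters. No test separated the 2, so a change within the remaining clusters is not excluded.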

How the results depend on the processing

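Classes by cluster, with and without clusters of shares over 4-fold apart and with random cells left out, and batch 1 shares by cluster calls were chosen after the result was seen.

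None of the 10 named matrix rows reversed direction under the alternatives run, and all lost their call when the batch block was left out. Not every alternative gave a result for each row, and the number that did ran from 8 for row 16829 to 12 for row 2224. The DESeq2 Wald test gave no adjusted p for rows 4879, 7087 and 29731. The ranges given for single rows leave missing results out. For each moved value the cause was not tested, except where noted. The CD45- class, with 1048 calls, gave 1939 with DESeq2 size factors, 640 with the DESeq2 Wald test, 379 and 623 with minimums of 500 and 2000 features and 478 with classes by cluster. The CD45+CD64+ class, with 1643, gave 655 with the DESeq2 Wald test, 998 with sums thinned, and 178 without clusters of shares over 4-fold apart. The CD45+CD64- class, with 67, gave 239 with no count filter, 160 with doublets kept, 1616 with a minimum of 2000 features, 225 with a class probability of at least 0.9, 681 with classes by cluster, 23 without clusters of shares over 4-fold apart and 316 with random cells left out. With sums thinned, edgeR called 0 there (390 at an unadjusted p under 0.05, 100 by the DESeq2 Wald test on unthinned sums). Without the batch block edgeR called 0 in the CD45-, CD45+CD64+ and CD45+CD64- classes (126, 892 and 80 at an unadjusted p under 0.05, and 640, 655 and 100 by the DESeq2 Wald test with batch). No fit leaving out a batch was run, since 1 sum per genotype would leave no residual degrees of freedom, and values within batches are given instead.

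The batch 1 share of the CD45+CD64+ class was 7.87% in WT and 5.80% in CD64-hDTR with WT libraries as reference, 6.33% and 6.34% with CD64-hDTR libraries, 7.74% and 7.18% by nearest centroid, 7.24% and 7.90% with a minimum of 2000 features, 8.31% and 8.23% with cells thinned, 8.01% and 6.97% by joint clusters and 7.98% and 6.95% by cluster calls. With doublets kept it was 10.7% in WT. The joint clusters put 71.6% of WT and 46.4% of CD64-hDTR batch 1 cells in the CD45+CD64- gate. The main classifier put 5.71% and 7.95% there. Most batch 1 cells lay in joint clusters with few batch 2 cells, so shares by joint clusters are of limited use. With a minimum of 500 features, the shares placed in their own gate were 97.0% for WT CD45-, 37.8% for WT CD45+CD64-, 87.2% for CD64-hDTR CD45-, 43.9% for CD64-hDTR CD45+CD64+ and 93.9% for CD64-hDTR CD45+CD64-. The difference for joint cluster 3 was -25.4 points at a resolution of 1.0 and -23.5 points with batches clustered separately. With the latter it was 19.0 points for cluster 10, and -7.15 points for cluster 5 in the CD45+CD64- gate. The correlation between batches in the CD45+CD64- class was 0.25 with classes by cluster and 0.39 with at least 1000 counts as well. Differences under 0.1 were taken as unchanged for correlations, a limit set after seeing the data.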

Other observations

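No test was run for the values below, which were picked after the result was seen. In the unsorted libraries, joint cluster 7 held 15.5% (14.8 to 16.2) of WT and 6.61% (5.93 to 7.36) of CD64-hDTR cells, and joint cluster 11, of the CD45+CD64+ type, held 7.21% (6.73 to 7.71) and 3.54% (3.03 to 4.10). Other joint clusters of this type were higher in CD64-hDTR there, cluster 3 at 0.0274% and 1.57%, and cluster 13 at 0.265% (0.177 to 0.380) and 1.28% (0.978 to 1.64), while the intervals of clusters 10, 16 and 18 overlapped. Cluster 11 also held less of the CD64-hDTR CD45+CD64+ gate, at 6.51% (5.78 to 7.29) in WT and 4.45% (3.80 to 5.17) in CD64-hDTR. Intervals are exact binomial ones over 1 library each and cover counting error only.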
